A study of Mus musculus with 2 samples.

How the data were processed

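The data came from the small intestinal epithelium of 1 mouse, aged 55 weeks, that carried a mutation in TrnA, the mitochondrial DNA (mtDNA) gene for the alanine tRNA that is listed as mt-Ta in the gene annotation, at a mutation load of 73%, per the labels. Both samples of the series are libraries made from the same cells: a gene expression library and an ATAC library, which reads where chromatin is open. Per the labels' protocols, villi and crypts were released with EDTA, digested with TrypLE and stained with antibodies to CD45, CD31, TER-119 and CD326 (Epcam, an epithelial surface protein) before flow sorting. The gates are not stated, so the shares of cell classes are those of the sorted suspension. The sorted cells were fixed with formaldehyde and processed with the 10x Multiome kit, with an added step adapted from DOGMA-seq that retains mtDNA, per the labels' protocols. No other animal was analysed here, so each comparison sets cell classes of this mouse side by side and none measures the effect of the mutation.

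The values in the deposited matrix are raw counts, per the file headers a Cell Ranger ARC output, with UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule) for 55401 genes and counts in 146191 peaks for 12363 barcodes. Cell Ranger ARC 2.0.2 and the mm10 genome build are named in the submitters' processing notes, and the matrix header names the same software version. The matrix held 71697164 UMIs and 197564789 counts in peaks. Of the deposited peak values above 0, 87.6% were even numbers, so they were read as cut sites, and each was divided by 2 and rounded up to fragments. The minimum of 1000 peak counts per cell had first been applied to fragments and was then set on the deposited counts, as its wording fixed before the data were examined required. Other peak analyses used fragments. Of the listed marker and program genes, 872 were found by symbol and 5 were not.

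Barcodes were kept with at least 500 UMIs, 300 genes and 1000 counts in peaks. Of 12363 barcodes, 12163, 10073 and 12072 passed these filters in turn and 9872 passed all of them. No ceiling was set on mtDNA-encoded UMIs, because they are a readout in this mutant. Doublets were scored with Scrublet (through scanpy 1.11.5), whose automatic threshold of 0.478 marked 1 of 9872 cells (0.0101%). A caller that marks so few cells has not worked, so doublets remain among the 9871 kept cells. An alternative added after the data were seen removed the 884 cells at or above the score that bounds the highest 8%, more than 8% of cells because scores were tied.

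Cells were clustered on RNA from a seeded random subset of 27320 genes, while 28081 genes were held out. All genes of the 33 program lists, all mtDNA genes and Lars2 were among those held out. Genes seen in at least 10 cells were ranked by Pearson residual variance, and the 1500 highest were scaled to nuclear-encoded UMIs, log-transformed and reduced to 30 principal components. A shared-neighbour graph over 15 neighbours was partitioned with the Leiden algorithm at resolution 1 (10 iterations, seed 1). Clusters were named from 15 marker lists fixed before the data were examined. The naming rule was set after the clusters had been seen: the median log2 ratio of a list against all other kept cells had to reach 0.4 (with 5 UMIs per 1000000 added), to exceed the next lineage by 0.4 and to rest on at least 3 detected markers. A cluster whose median of nuclear-encoded UMIs was over 3 times below that of all kept cells also needed 2 of its own markers among its 10 leading genes. This rule left 2117 cells (21.4%) unnamed, and they belong to no class. Crypt progenitor-like cells are the stem-like and cycling-like clusters together.

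Each of the 5 other classes was compared with enterocyte-like cells by summing UMIs per class. The scale fixed before the data were examined was UMIs per 1000000 UMIs of all kinds, and an alternative fixed at the same time left mtDNA-encoded UMIs out of the library size. The choice matters here, since mtDNA-encoded RNA took most of the UMIs of many cells. On the scale of all UMIs every ratio lies higher than on the nuclear-encoded scale by a log2 of 1.10 for crypt progenitor-like, 1.17 for goblet-like, 1.49 for Paneth-like, 1.31 for enteroendocrine-like and 1.09 for tuft-like cells. Gene lists are given on both scales. Named genes are given per nuclear-encoded UMI unless stated otherwise, beside the log2 ratio of the median nuclear gene. A member of a list was counted as higher or lower where its ratio was at least 1.5-fold and its 95% counting interval excluded no change, among members with at least 20 UMIs over both classes. The percentile of a list's median was taken among 10000 random lists of the same size matched on mean expression, and it describes these libraries only. Genes are not independent replicates, and intervals of list medians in the plots are order statistics over the members.

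With 1 animal there are no replicates, no p-value is given, and no genome-wide number of changed genes was made. Intervals are exact (Clopper-Pearson for shares, conditional binomial for ratios, Poisson for levels) at 95% and cover counting error only. Against a count of 0, a fold was computed with a floor of 3 counts over the class. For each list described in detail, up to 4 members with the largest ratio and at least 50 UMIs were named by a rule fixed before the data were examined. The same rule named the 6 highest and 6 lowest held-out genes outside all lists by the interval bound nearest no change, among genes with at least 100 UMIs, and the 2 leading peaks of each class with at least 100 counts. Predicted genes, including genes known only by a clone name, were left out. Fewer members are printed for some lists, and a gene that the rule names is not reported here. The lists described in detail were chosen after the values of all 33 had been seen.

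A promoter peak overlapped the interval of a gene's annotated transcription starts, widened by 1 kb on each side. For a gene with several starts, peaks between these starts were thus counted as promoter peaks too. Peak coordinates are those of the deposited features on mm10, counted from 1. Motifs in leading peaks were planned and not run, because no genome sequence was used here. Genes with near-identical copies are uncertain because the counting may have split or dropped shared reads: this concerns the defensin genes, Gsdmc2 to Gsdmc4, H2-Q1 and H2-Q2, Slc5a4a, Reg3b, Reg3g and the respiratory chain genes with processed pseudogenes, and overlapping mt-Atp8 and mt-Atp6 or mt-Nd4l and mt-Nd4. Lars2, whose counts are very high in all classes, is uncertain as well.

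On simulated counts with the depths of the real classes, genes changed 2-fold in the crypt progenitor-like contrast (13059 genes) were recovered with a median log2 of 1.00, and 86.6% met the 1.5-fold criterion against 1.06% of unchanged genes. In the tuft-like contrast (10577 genes) 32.8% of genes changed 2-fold met it. The simulated counts were Poisson draws around class sums per UMI of all kinds, without variation between cells, free RNA or doublets. These percentages thus cover counting error only and are not error rates of the real comparisons. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Alternatives planned before the data were examined varied the UMI minimum, doublet removal, mtDNA ceiling (20%), cluster resolution (0.5 and 2), the assay that makes the clusters, the weight of cells, depth, library size, the gene minimum and the promoter window. A ceiling of 80%, removal of these 884 cells and the nuclear-encoded scale for held-out genes were added after the data were seen.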

Results

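Single epithelial cells from the small intestine of 1 mouse with a mutation in the mitochondrial alanine tRNA gene (TrnA) were profiled for RNA and open chromatin in the same droplets. The series concerns how a mutation in mtDNA affects intestinal epithelial cells during acute colitis. Whether this animal had colitis is not stated, and a control animal was not analysed here. The 2 libraries held 71697164 UMIs and 197564789 counts in peaks. The 9871 kept cells had medians of 5591 UMIs, 1547 nuclear-encoded UMIs, 1090 genes and 12884 counts in peaks. All values come from 1 animal without replicates, and intervals cover counting error only.

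Absorptive, secretory and progenitor cells of the intestinal epithelium were found among the kept cells. Enterocyte-like cells, the absorptive cells of the villus, were the most frequent named class with 3591 cells (36.4%, 95% exact interval 35.4 to 37.3%). Crypt progenitor-like cells numbered 2088 (21.2%, 20.4 to 22.0%), of which 838 were stem-like, in a cluster led by the intestinal stem cell genes Lgr5 and Smoc2, and 1250 were cycling-like, in a cluster of 861 cells led by mitotic genes such as Knl1 and Cenpe and a cluster of 389 cells led by Nol8, Mki67 and Snhg5. This split depends on the clustering: with the 1 marked doublet kept, 847 cells were cycling-like, and at Leiden resolution 0.5 a single cluster of 2157 cells took the stem-like name and none was cycling-like. Goblet-like cells, which secrete mucus, numbered 1469 (14.9%, 14.2 to 15.6%) and Paneth-like cells, which secrete antimicrobial proteins such as Lyz1, numbered 283 (2.87%, 2.55 to 3.21%). Enteroendocrine-like cells, which secrete hormones, numbered 204 (2.07%, 1.79 to 2.37%) and tuft-like cells, the chemosensory Dclk1-expressing cells, numbered 96 (0.973%, 0.788 to 1.19%). A cluster of 23 cells led by Dock2 and Ptprc, the gene for CD45, was lymphocyte-like (0.233%, 0.148 to 0.349%). The remaining 2117 cells (21.4%) were left unnamed by the naming rule.

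Marker genes of secretory lineages were also counted in other classes. Paneth markers made up 207496 UMIs per 1000000 nuclear-encoded UMIs in Paneth-like cells, 6764 in enterocyte-like cells and 2567 in crypt progenitor-like cells. Goblet markers made up 60469 per 1000000 in goblet-like cells, 14635 in Paneth-like cells, 10680 in the 23 lymphocyte-like cells (95% exact interval 9542 to 11916) and 7819 in enterocyte-like cells. Enterocyte markers stood at 36073 per 1000000 in enterocyte-like, 7950 in goblet-like and 3863 in crypt progenitor-like cells. Markers of T cells and intraepithelial lymphocytes stood at 5307 per 1000000 in lymphocyte-like cells, below the goblet markers there, and at most 409 per 1000000 in the 6 epithelial classes. The class shares depend on how clusters were made: with clusters from the ATAC peaks, Paneth-like cells made up 6.74%, goblet-like cells 7.11% and enteroendocrine-like cells 3.13% of kept cells. With cells above 80% mtDNA-encoded UMIs left out, an alternative added after the data were seen, enterocyte-like cells made up 13.2%, Paneth-like cells 3.90% and tuft-like cells 1.58%.

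The mutated tRNA gene lies in mtDNA, and mtDNA also encodes 13 mRNAs for respiratory chain subunits and the mitochondrial rRNAs. The RNA of enterocyte-like cells held the highest share of these mRNAs among the 6 epithelial classes. They made up 16.0% of UMIs in enterocyte-like cells (95% exact interval 16.0 to 16.1%), 10.6% in tuft-like (10.5 to 10.7%), 8.72% in goblet-like (8.71 to 8.74%), 7.92% in Paneth-like (7.88 to 7.96%), 7.24% in enteroendocrine-like (7.19 to 7.29%) and 4.59% in crypt progenitor-like cells (4.58 to 4.60%). The share in enterocyte-like cells was thus 3.49-fold that in crypt progenitor-like, 2.21-fold that in enteroendocrine-like, 2.03-fold that in Paneth-like, 1.84-fold that in goblet-like and 1.51-fold that in tuft-like cells. In molecules per cell, enterocyte-like cells carried a mean of 955 mtDNA-encoded mRNA UMIs against 329 in crypt progenitor-like, 370 in enteroendocrine-like, 486 in Paneth-like, 616 in goblet-like and 651 in tuft-like cells. The medians were 669 in enterocyte-like, 179 in crypt progenitor-like, 218.5 in enteroendocrine-like, 184 in Paneth-like, 223 in goblet-like and 447 in tuft-like cells. The goblet-like mean includes a cluster of 265 cells with high doublet scores, described further on, with a mean of 1492.

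Mitochondrial rRNA took 63.3% of UMIs in enterocyte-like, 51.2% in crypt progenitor-like, 45.4% in tuft-like, 44.7% in goblet-like, 41.3% in enteroendocrine-like and 33.9% in Paneth-like cells. The ratio of mtDNA-encoded mRNA to mitochondrial rRNA was 0.0897 in crypt progenitor-like cells and between 0.175 and 0.253 in the other 5 classes. Nuclear-encoded UMIs per cell were 2.57-fold higher in crypt progenitor-like than in enterocyte-like cells and 2.14 to 2.90-fold higher in the secretory classes. With cells above 80% mtDNA-encoded UMIs left out, a limit on a share that includes these mRNAs, the share of mtDNA-encoded mRNA in enterocyte-like cells was 9.40%, against 9.39% in tuft-like and 4.37% in crypt progenitor-like cells.

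**Figure D1:**
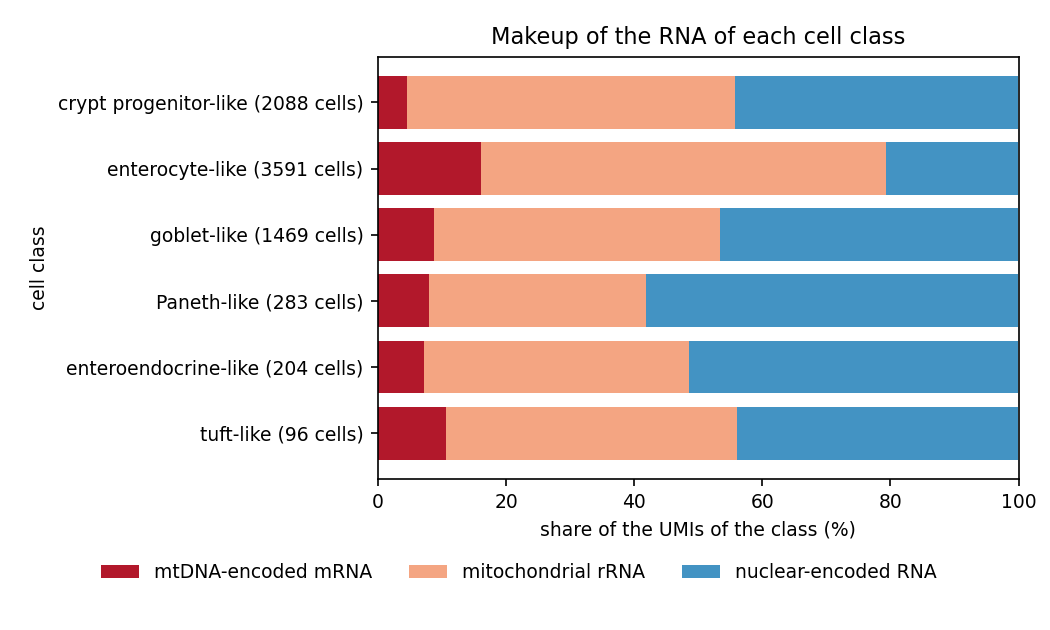
Share of all UMIs (x axis, percent, summed over the cells of a class) from mtDNA-encoded mRNA, mitochondrial rRNA and nuclear-encoded RNA in each of 6 epithelial cell classes (y axis, with cell numbers); counting intervals are too narrow to draw. Nuclear-encoded RNA took 20.7% of UMIs in enterocyte-like cells and 44.0 to 58.2% in the other classes.

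Crypt progenitor-like cells, which renew the epithelium, were compared with enterocyte-like cells to ask how mitochondrial and other programs differ between dividing and absorptive cells. Crypt progenitor-like cells held less of all 13 mtDNA-encoded mRNAs, less of the genes for lipid and nutrient uptake, antigen presentation and interferon response, and more of the nuclear genes that maintain, transcribe and decode mtDNA. Per nuclear-encoded UMI the 13 mRNAs had a median log2 ratio of -2.80, from -3.06 for mt-Co3, a cytochrome c oxidase subunit, to -2.55 for mt-Nd6, a complex I subunit. Per UMI of all kinds the median was -1.70, and -0.96 with cells above 80% mtDNA-encoded UMIs left out. The nuclear-encoded subunits of the respiratory chain moved far less, and their direction depends on the scale. The median nuclear gene stood at 0.50 per nuclear-encoded UMI and at 1.59 per UMI of all kinds.

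Per nuclear-encoded UMI, the 36 nuclear subunits of complex I (NADH dehydrogenase) had a median of -0.21, with 0 members higher and 5 lower, at percentile 1.33 of random lists. The lowest were Ndufa1 at -0.88, Ndufa11 at -0.85, Ndufa6 at -0.82 and Ndufa13 at -0.75. Complex III (ubiquinol-cytochrome c reductase) stood at -0.39, with 0 higher and 3 lower of 9 and Uqcrb lowest at -1.0. Complex IV (cytochrome c oxidase) stood at -0.47, with 0 higher and 1 lower of 11, the lowest named member being Cox7a2 at -0.69. Complex V (ATP synthase) stood at -0.39, with 2 higher and 2 lower of 15. Atp5g2 stood at 1.54 and Atp5o at 1.36, while Atp5e stood at -0.78 and Atp5d at -0.72. Per UMI of all kinds the medians turned positive, at 0.88 for complex I, 0.71 for complex III, 0.63 for complex IV and 0.71 for complex V, all below the median gene. With cells above 80% mtDNA-encoded UMIs left out, the medians per UMI of all kinds were -0.020 for complex III and -0.029 for complex IV.

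The 17 mitochondrial aminoacyl-tRNA synthetases, which charge mitochondrial tRNAs with amino acids, had a median log2 of 1.38 per nuclear-encoded UMI and 2.48 per UMI of all kinds. Of them, 15 were higher and 0 lower, at percentile 98.2, with Yars2 at 3.05 (149 against 12 UMIs), Ears2 at 2.56, Vars2 at 2.41 and Mars2 at 2.36. Genes of mitochondrial tRNA processing and modification stood at 1.37 and 2.46, with 11 higher and 0 lower of 15, at percentile 96.3. Among them were Trit1, a tRNA isopentenyltransferase, at 2.41, the tRNA methyltransferases Trmt61b at 2.29 and Trmt5 at 1.96, and Prorp, the catalytic subunit of mitochondrial RNase P, at 2.11. Genes of mtDNA maintenance and transcription stood at 1.2 and 2.30, with 16 higher and 2 lower of 22, at percentile 98.4. The nucleases Mgme1 and Exog stood at 3.29 and 3.17 and the rRNA methyltransferase Tfb1m at 2.71, while Ppargc1a, a coactivator of mitochondrial biogenesis, stood at -2.82 (420 against 1981 UMIs). Mitochondrial ribosomal proteins had a median of 0.40, below the median gene, and 1.49 per UMI of all kinds, with 31 higher and 1 lower of 76. Mrps27 stood at 3.11 (401 against 31 UMIs), Mrps9 at 1.82, Mrpl19 at 1.77 and Mrps22 at 1.72.

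Genes of the integrated stress response, the translational control program that acts through Atf4, had a median of 0.30 per nuclear-encoded UMI and 1.39 per UMI of all kinds, at percentile 19.8, with 10 higher and 4 lower of 25. The members with the largest ratios were Phgdh and Psat1 of serine synthesis at 3.54 (counting interval 1.91 to 5.86, 52 against 3 UMIs) and 2.23, the amino acid transporter Slc7a5 at 2.88 and Pck2 at 2.05. The 4 lower members, named after their values were seen, were Trib3 at -4.39 (counting interval -6.72 to -2.74, 3 against 42 UMIs), Ddit3 at -1.98, Slc3a2 at -1.24 and Atf3 at -0.59. Fatty acid oxidation and ketogenesis stood at 0.15 and 1.24, with 4 higher and 5 lower of 24. Cpt1a, which brings fatty acids into mitochondria, stood at 1.80, Bdh1 at 1.07 and Pdk4 at -2.61.

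Genes of lipid uptake and chylomicron assembly had a median of -3.00 per nuclear-encoded UMI and -1.90 per UMI of all kinds, with 1 higher and 20 lower of 22, below all random lists. Among them were Apob, the structural protein of chylomicrons, at -4.02 (1364 against 14806 UMIs), the transcription factor Creb3l3 at -4.10 and the fatty acid transporters Cd36 at -4.09 and Slc27a4 at -3.78. Nutrient and ion transporters stood at -3.38 and -2.28, with 0 higher and 21 lower of 23, led by Slc13a2 at -5.46, Slc23a1 at -5.00, Slc6a19 at -4.81 and Slc2a2 at -4.77. The size of this median depends on the clusters: it was smaller with clusters from ATAC peaks, as given with the alternatives. The MHC class II presentation list stood at -2.16 and -1.06, with 0 higher and 8 lower of 9. Of its named members H2-Aa (-2.92) and H2-Ab1 (-2.61) are class II genes, while H2-Q1 (-3.90) and H2-Q2 (-2.72) are class I-type genes. The interferon response list stood at -1.82 and -0.72, with 1 higher and 19 lower of 24. Zbp1 stood at -4.78, Ifit1 at -4.26 and Rsad2 at -4.14, while Cgas, the sensor of cytosolic DNA, stood at 4.82 (254 against 6 UMIs). Wnt targets and signalling genes stood at 1.42 and 2.52, with 12 higher and 2 lower of 15, at percentile 99, led by Ephb3 at 3.80, Ephb2 at 3.77, Cd44 at 3.12 and Ccnd1 at 2.38.

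Of the lists not described in detail, Notch signalling had a median of 1.29 per nuclear-encoded UMI and mitochondrial chaperones and proteases 0.90, with 10 higher and 3 lower of 14 and 10 higher and 0 lower of 16. The distal and proximal segment lists stood at -3.27 and -2.64, the villus tip and base landmarks at -2.96 and -1.5, and NF-kB and inflammatory genes at -1.54. Smaller medians were those of tight junction and adhesion genes (-0.67), apoptosis and p53 (-0.53), glycolysis and lactate (-0.40), antioxidant and glutathione genes (-0.29), dissociation and immediate early genes (-0.26), mitophagy and dynamics (-0.26) and complex II (-0.039), all of which turned positive per UMI of all kinds. The tricarboxylic acid cycle stood at 0.11, epithelial transcription factors at 0.058 and the unfolded protein response of the endoplasmic reticulum at 0.049.

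Among held-out genes outside all lists, those highest in crypt progenitor-like cells included Cyyr1 (58.8-fold per nuclear-encoded UMI), the serotonin receptor gene Htr4 (52.0-fold, 1867 against 24 UMIs), the DNA repair polymerase Polq (48.9-fold), Sorbs2 (34.6-fold) and the orphan nuclear receptor Esrrg (30.3-fold, 9108 against 201 UMIs). Fancb, of the Fanconi anaemia DNA repair pathway, was at least 38.6-fold higher at a floor of 3 counts (173 against 0 UMIs), and the log2 interval from the counts began at 4.96. The genes highest in enterocyte-like cells were Slc5a4a (49.0-fold), Abi3bp (47.2-fold), Pdzk1, a scaffold of brush border transporters (37.7-fold), the monocarboxylate transporter Slc5a12 (35.1-fold), Slc47a1 (35.0-fold) and Tmprss15, the enteropeptidase that activates trypsinogen (27.6-fold).

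**Figure D2:**
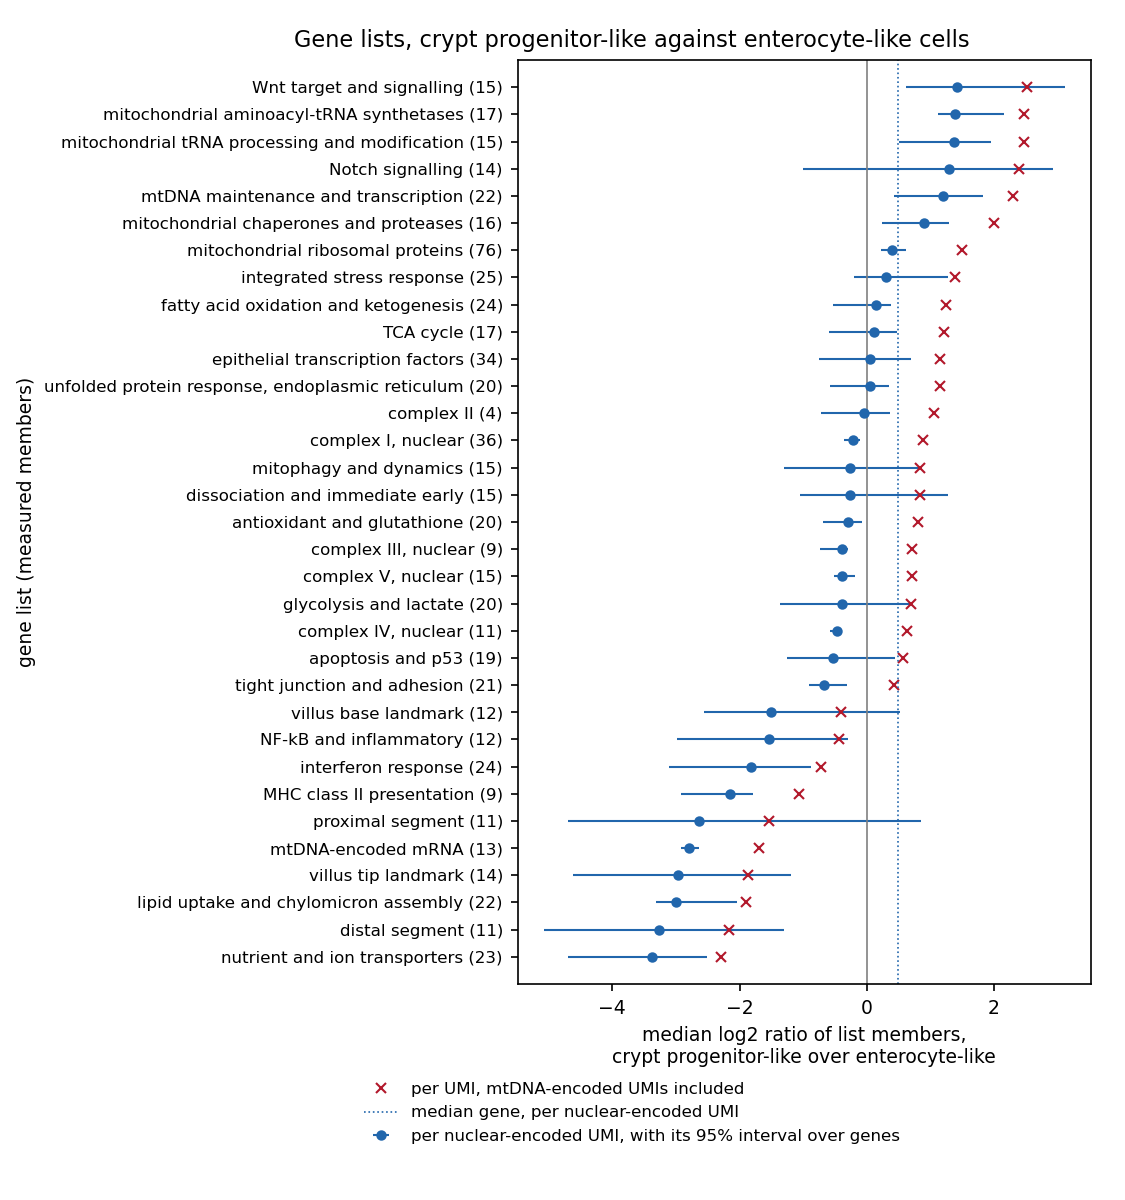
Median log2 ratio of crypt progenitor-like over enterocyte-like cells (x axis) for each of 33 gene lists (y axis, with the number of measured members); dots with 95% intervals over members (the range for complex II, with 4 members) are per nuclear-encoded UMI, crosses are per UMI of all kinds and the dotted line marks the median nuclear gene at 0.50. Medians ran from -3.38 for nutrient and ion transporters to 1.42 for Wnt targets per nuclear-encoded UMI, and lists with medians from -0.67 to 0, complex I among them, turned positive per UMI of all kinds.

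Goblet-like cells, which fill with mucins made in the endoplasmic reticulum, held more of the genes of the unfolded protein response of the endoplasmic reticulum and of the integrated stress response list than enterocyte-like cells, and less mtDNA-encoded mRNA, lipid handling and MHC class II mRNA. Genes of the unfolded protein response had a median log2 of 0.95 per nuclear-encoded UMI and 2.12 per UMI of all kinds, with 14 higher and 0 lower of 20, at percentile 99.99. Ern2, the stress sensor of mucus-secreting cells, stood at 5.60 (1166 against 22 UMIs), the folding factors Pdia6 and Hyou1 at 1.61 and 1.60, and the transcription factor Xbp1 at 1.49. The integrated stress response list stood at 0.73 and 1.90, with 14 higher and 2 lower of 26, at percentile 97.9, and held the asparagine synthetase Asns at 2.44, the amino acid transporters Slc7a5 at 2.52 and Slc7a11 at 2.14, and the lipoprotein receptor Vldlr at 3.65. With each cell thinned to 500 UMIs its median per UMI of all kinds was 0.77. Without thinning, no change per nuclear-encoded UMI lies at 1.17 on that scale and the median nuclear gene at 1.37. The thinned value lies below both, so the higher median of this list depends on depth.

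In the same cells the 13 mtDNA-encoded mRNAs stood at -2.04 and -0.87, all lower on both scales, from -2.13 for mt-Nd6 to -2.01 for mt-Nd2. Without cells above 80% mtDNA-encoded UMIs, the goblet-like medians per UMI of all kinds were -0.19 for these mRNAs, 0.016 for complex I and -1.28 for lipid uptake. Nuclear complex I genes stood at -0.49, with 0 higher and 14 lower of 36 (Ndufa1 -0.96, Ndufa5 -0.93, Ndufb4 -0.86, Ndufs7 -0.83), and turned to 0.68 per UMI of all kinds, below the median gene at 1.37. Mitochondrial aminoacyl-tRNA synthetases stood at 0.66 and 1.84, with 8 higher and 0 lower of 16, led by Yars2 at 1.96, Wars2 at 1.84, Mars2 at 1.67 and Ears2 at 1.46. Lipid uptake and chylomicron genes stood at -1.80 and -0.63, with 0 higher and 20 lower of 22 (Apob -2.68, Creb3l3 -2.62, Cd36 -2.42, Apoc3 -2.40), and the MHC class II list at -1.91 and -0.74, with 9 of 9 lower (H2-Q1 -3.01, Ciita -2.17, H2-Eb1 -2.17, H2-Aa -2.03). The median nuclear gene stood at 0.20. Among held-out genes Sidt1 was 66.5-fold higher, Cd200 61.3-fold, Srgap1 57.1-fold, Ano7 55.8-fold, Rhobtb1 49.4-fold and Ptprn2 43.7-fold. Those lower were Hspa12a (12.7-fold), the procollagen protease Bmp1 (12.2-fold), Slc5a12 (8.22-fold), Efr3b (7.5-fold), Tmprss15 (7.08-fold) and Pdzk1 (6.59-fold). A goblet-like cluster of 265 cells with high doublet scores held 2.24 times the level of lipid and transporter genes of the largest goblet-like cluster, which bears on the size of these lower values. At Leiden resolution 0.5 it was not a separate cluster.

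Paneth-like cells, which store antimicrobial proteins in granules, held more of the genes of the unfolded protein response than enterocyte-like cells, and less mtDNA-encoded mRNA. Unfolded protein response genes stood at 0.75 per nuclear-encoded UMI and 2.25 per UMI of all kinds, with 14 higher and 0 lower of 20, at percentile 99.97 (Ern2 5.13, Pdia6 1.86, Ern1 1.5, Hyou1 1.33). The integrated stress response list stood at 0.72 and 2.21, with 10 higher and 5 lower of 24, at percentile 99.2, led by Vldlr at 4.50, Slc7a5 at 3.83, Asns at 3.20 and the mitochondrial folate enzyme Mthfd2 at 2.13. With each cell thinned to 500 UMIs its median per UMI of all kinds was 0.27, and with at least 100 UMIs per gene it was 1.14. No change per nuclear-encoded UMI lies at 1.49 on the scale of all UMIs, and the median nuclear gene at 1.36. The higher median of this list thus rests on members with few UMIs, and with at least 100 UMIs per gene it fell below 0 per nuclear-encoded UMI. The 13 mtDNA-encoded mRNAs stood at -2.49 and -1.0, all lower, from -2.59 for mt-Nd5 to -2.39 for mt-Nd6. Without cells above 80% mtDNA-encoded UMIs, the Paneth-like medians per UMI of all kinds were -0.23 for these mRNAs, 0.041 for complex I and -2.24 for lipid uptake.

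In Paneth-like cells, nuclear complex I genes stood at -0.72, with 0 higher and 22 lower of 36 (Ndufs5 -1.47, Ndufa9 -1.44, Ndufb9 -1.44, Ndufa6 -1.13), and turned to 0.77 per UMI of all kinds, below the median gene at 1.36. Per nuclear-encoded UMI that median gene stood at -0.13. Mitochondrial aminoacyl-tRNA synthetases stood at 0.77 and 2.26, with 8 higher and 0 lower of 16 (Nars2 1.57, Wars2 1.40, Rars2 0.85, and the uncertain Lars2 0.95). Lipid uptake genes stood at -2.76 and -1.26, with 0 higher and 20 lower of 22, and included Mogat2, which makes diacylglycerol from absorbed fat, at -5.02 (counting interval -7.31 to -3.47, 3 against 427 UMIs), Gpat3 at -3.60, Creb3l3 at -3.44 and Cd36 at -3.42. The MHC class II list stood at -2.45 and -0.96, with 9 of 9 lower (H2-Eb1 -2.83, H2-Q1 -2.83, Ciita -2.57, H2-Aa -2.54). Held-out genes highest in Paneth-like cells were Tent5c (156-fold), Thsd7a (119-fold), Habp2 (95.2-fold), Thbs1 (86.5-fold), Sidt1 (73.0-fold) and Tanc2 (64.5-fold), and those lowest were Slc22a4 (29.7-fold lower), Slc5a12 (24.3-fold), Pdzk1 (19.9-fold), Mme (14.5-fold), Clec2e (14.1-fold) and Xdh (13.6-fold).

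Enteroendocrine-like cells, the hormone-producing cells, held less mtDNA-encoded mRNA, less nuclear complex I mRNA per nuclear-encoded UMI and less of the lipid and antigen presentation genes than enterocyte-like cells. The 13 mtDNA-encoded mRNAs stood at -2.38 per nuclear-encoded UMI and -1.06 per UMI of all kinds, all lower, from -2.53 for mt-Atp6 to -2.18 for mt-Nd5. Without cells above 80% mtDNA-encoded UMIs, the enteroendocrine-like medians per UMI of all kinds were -0.28 for these mRNAs, 0.049 for complex I and -2.26 for lipid uptake. Nuclear complex I genes stood at -0.57, with 0 higher and 16 lower of 36 (Ndufs8 -1.76, Ndufb3 -1.66, Ndufv1 -1.26, Ndufa2 -1.08), and turned to 0.75 per UMI of all kinds, below the median gene at 1.5. The median gene was 0.18 per nuclear-encoded UMI. Mitochondrial aminoacyl-tRNA synthetases stood at 0.80 and 2.11, with 7 higher and 1 lower of 15, led by Nars2 at 3.01 (85 against 87 UMIs), Wars2 at 2.04, Fars2 at 1.5 and Rars2 at 0.87.

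In enteroendocrine-like cells the integrated stress response list stood at 0.047 and 1.36, with 7 higher and 2 lower of 22, at percentile 26.7. Ddit3, the stress-induced transcription factor CHOP, stood at -3.31 (counting interval -6.36 to -1.43, 2 against 163 UMIs) and Slc3a2 at -1.37, while the tRNA synthetase Gars stood at 2.33 and Mthfd2 at 1.46. Unfolded protein response genes stood at 0.36 and 1.67, with 4 higher and 3 lower of 20 (Edem1 -1.42, Dnajb9 -1.07, Ern1 1.04, Atf6 0.80). Lipid uptake genes stood at -2.59 and -1.27, with 2 higher and 19 lower of 23. Scarb1, a receptor for high-density lipoprotein, stood at 4.78, against Creb3l3 at -3.77, Gpat3 at -3.61 and Apob at -3.46. The MHC class II list stood at -2.81 and -1.49, with 8 of 9 lower, including H2-DMb1 at -4.34 (-9.65 to -1.84, 1 against 167 UMIs), H2-Eb1 at -3.60 and H2-Aa at -3.31. Held-out genes highest in this class were Adcy2 (1241-fold), the transcription factor Lmx1a (882-fold, log2 interval 7.91 to 12.84, 214 against 2 UMIs), the growth factor Nrg1 (861-fold), the sodium channel Scn3a (445-fold), the calcium channel Cacna1c (349-fold) and Ptprn2, a protein of secretory granules (319-fold). Those lowest were Efr3b (35.9-fold lower, log2 interval -8.21 to -3.31, 2 against 591 UMIs), Tmprss15 (23.2-fold), Mpp1 (21.6-fold), Cndp2 (16.4-fold), Xdh (16.1-fold) and Slc5a12 (15.9-fold).

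Tuft-like cells, the smallest epithelial class with 96 cells, came closest of the 5 classes to enterocyte-like cells in mtDNA-encoded mRNA. The 13 mRNAs had a median log2 of -1.60 per nuclear-encoded UMI, with 13 lower, and -0.51 per UMI of all kinds, with 5 lower, from -1.90 for mt-Atp8 to -1.2 for mt-Nd6 on the nuclear-encoded scale. With cells above 80% mtDNA-encoded UMIs left out, the median per UMI of all kinds was 0.048 and that of the integrated stress response list -0.51. Nuclear complex I genes stood at -0.32, with 0 higher and 7 lower of 36 (Ndufs6 -1.03, Ndufb7 -1.02, Ndufab1 -1.0, and Ndufb4 -1.30 with a counting interval of -3.60 to 0.28 from 3 UMIs), and turned to 0.76 per UMI of all kinds, below the median gene at 1.31. The median gene was 0.22 per nuclear-encoded UMI.

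In tuft-like cells mitochondrial aminoacyl-tRNA synthetases stood at 0.51 and 1.60, with 5 higher and 0 lower of 13 (Wars2 1.90, Nars2 1.24, Rars2 1.2, Fars2 1.01). The integrated stress response list stood at 0.068 and 1.16, with 0 higher and 3 lower of 20, and among its members Slc3a2 and Atf3 both stood at -1.46. These medians are upper limits, since 4 members with 0 UMIs in tuft-like cells entered at the floor of 3 counts, which lies above their level in enterocyte-like cells per nuclear-encoded UMI. Unfolded protein response genes stood at 0.21 and 1.30, with 4 higher and 1 lower of 20 (Creld2 1.87, Hsp90b1 1.22, Atf6 0.99, Edem1 -1.13). Lipid uptake genes stood at -3.06 and -1.97, with 0 higher and 18 lower of 21, including the sterol transporter Abcg5 at -4.78 (4 against 1878 UMIs), Slc27a4 at -4.16 and Apob at -3.48. With each cell thinned to 500 UMIs that median was -0.42 per UMI of all kinds. A member left with 0 tuft-like UMIs enters at the floor of 3 counts, which stands for a higher level at this depth, so this value is an upper limit. The MHC class II list stood at -2.93 and -1.84, with 8 of 9 lower, including H2-Ab1 at -3.05 and H2-Q2 at -2.98. Held-out genes highest in tuft-like cells were Rgs22 (1233-fold), the potassium channel Kcnd3 (1007-fold, log2 interval 8.09 to 13.04, 118 against 2 UMIs), the haematopoietic signalling genes Inpp5d (806-fold) and Vav1 (486-fold), the kinase Bmx (290-fold) and Dmxl2 (97.2-fold). Those lowest were Tmprss15 (44.8-fold lower, log2 interval -8.53 to -3.63, 2 UMIs), Pdzk1 (33.9-fold, -7.36 to -3.54, 3 UMIs), Slc5a12 (28.5-fold), Mme (20.3-fold), Xdh (17.8-fold) and Cyp3a13 (14.5-fold).

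**Figure D3:**
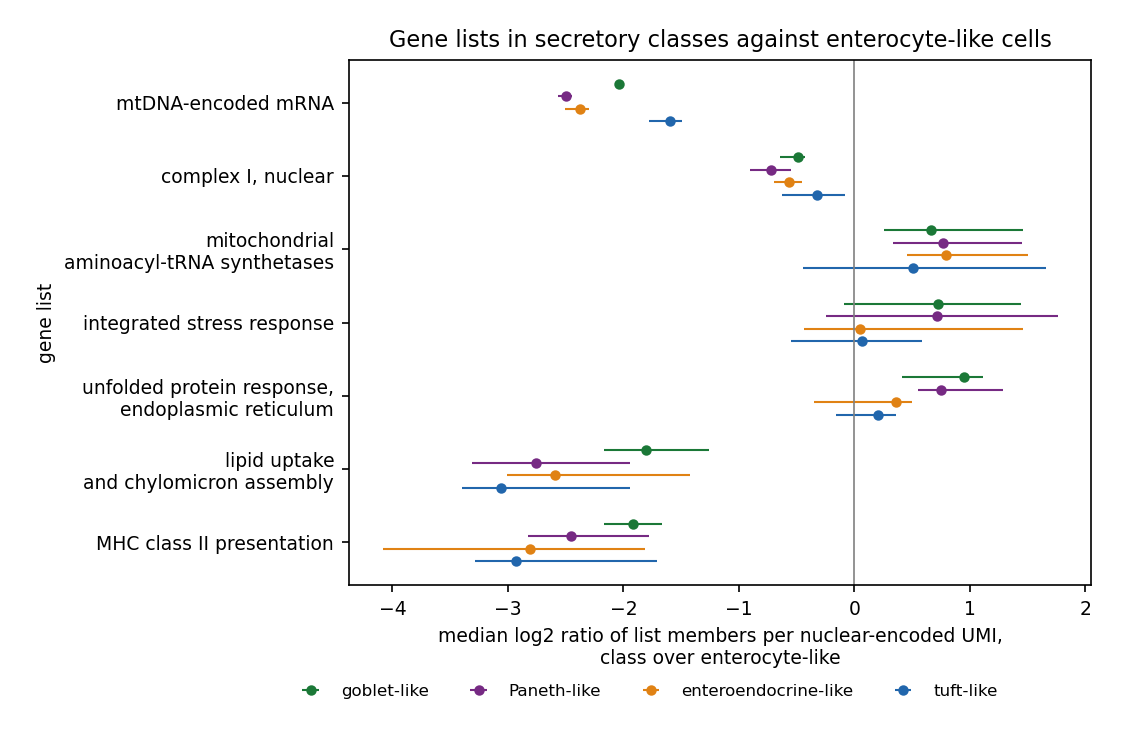
Median log2 ratio of 4 secretory classes over enterocyte-like cells per nuclear-encoded UMI (x axis) for 7 gene lists (y axis); dots are medians over list members and bars their 95% intervals over members. Nuclear complex I medians lay between -0.72 and -0.32 in all 4 classes on this scale and turned positive per UMI of all kinds, while unfolded protein response medians were 0.95 in goblet-like and 0.75 in Paneth-like cells.

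Other respiratory chain lists stood below the median gene in the 4 secretory classes per nuclear-encoded UMI. Complex III stood at -0.64 in goblet-like, -1.11 in Paneth-like, -0.91 in enteroendocrine-like and -0.74 in tuft-like cells, complex IV at -0.72, -0.98, -0.85 and -0.74, and complex V at -0.66, -0.96, -0.73 and -0.43, all positive per UMI of all kinds. Notch signalling stood at 1.13, 1.11, 0.57 and 0.44 and nutrient and ion transporters at -2.15, -3.04, -2.69 and -3.40 in the same order.

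The enterocyte-like clusters differed in villus and segment genes that had not shaped them. Relative to the other enterocyte-like cells and per nuclear-encoded UMI, a cluster of 752 cells held more of the villus tip landmarks (median log2 1.41, 11 higher and 1 lower of 14), among them the purine-metabolising enzymes Nt5e at 5.74 and Ada at 3.58, the receptor Egfr at 3.93 and Ifrd1 at 3.29. The same cells held less of fatty acid oxidation (-0.65, 13 of 21 lower) and more of immediate early genes (0.74, 9 of 14 higher). A cluster of 472 cells held more of the distal segment list (0.90, 8 higher and 2 lower of 11), led by the ileal bile acid transporter Slc10a2 at 3.67 and the bile acid binding protein Fabp6 at 2.79, and more of the MHC class II list (0.64, 5 of 9 higher), with H2-Aa at 1.23 and Cd74 at 0.89. A cluster of 274 cells held more of the proximal segment list (0.81, 9 of 11 higher), with Rbp2 of retinol uptake at 1.67, and less of the tip landmarks (-1.78, 12 of 14 lower).

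The largest cluster, of 2093 cells, had the highest share of mtDNA-encoded mRNA among the 4 enterocyte-like clusters, 19.4% of UMIs, against 13.5%, 11.8% and 10.2% in the tip, distal and proximal clusters. It also had the fewest nuclear-encoded UMIs, a mean of 806 per cell against 1074, 2481 and 2753 in the same order. Per cell it held a mean of 1069 mtDNA-encoded mRNA UMIs, against 699.7, 902 and 875. Per UMI of all kinds the ratios of the tip, distal and proximal clusters shift by 0.011, 0.83 and 0.73, which turns none of the list medians given here.

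Promoters of most marker genes were more open in the cells named by those markers' RNA, although chromatin had no part in the naming. The median log2 ratio to all other kept cells was 2.92 for goblet markers (15 of 15 promoters with an interval above 0), 2.16 for tuft (13 of 14), 1.86 for enteroendocrine (18 of 20), 1.86 for Paneth (6 of 7), 1.05 for stem (13 of 14), 0.71 for enterocyte (19 of 20) and 0.23 for cycling markers (12 of 16). The rise at cycling markers in crypt progenitor-like cells was not particular to them, since markers of tuft (0.32, 9 of 14), M (0.30, 5 of 9) and enteroendocrine cells (0.29, 10 of 20) stood as high there. Lists of non-epithelial cells, with 3 to 6 promoters each, stood higher, from 0.45 for stromal to 0.84 for T cell and intraepithelial lymphocyte markers. These lay below the stem markers at 1.05. Promoter peaks took 46.8% of fragments in enterocyte-like cells, 50.6% in goblet-like, 51.0% in crypt progenitor-like, 51.6% in Paneth-like, 54.1% in enteroendocrine-like and 55.6% in tuft-like cells.

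Gene lists were also read at promoters. In crypt progenitor-like against enterocyte-like cells, promoters of Wnt genes had a median log2 of 0.91 (17 of 20 with an interval above 0), Notch genes 0.63 (13 of 17), mtDNA maintenance genes 0.46 (14 of 22) and mitochondrial aminoacyl-tRNA synthetases 0.19 (11 of 17). The interval of the synthetase median over members reached from -0.0054 to 0.59. Promoters of mitochondrial ribosomal proteins, whose RNA lay below the median gene, stood at 0.26 (48 of 77). Nuclear complex I promoters stood at 0.22 (25 of 36 above 0) and NF-kB and inflammatory promoters at 0.30 (14 of 18), both opposite in sign to the RNA of the list per nuclear-encoded UMI. So were interferon response (0.094, 13 of 28 above 0 and 4 below), complexes III (0.079), IV (0.15) and V (0.26), and mitophagy (0.19). Apoptosis and p53 (0.16), glycolysis (0.15), antioxidant (0.093), tight junction (0.070) and villus base promoters (0.030) were opposite as well. The intervals over members of these further medians all included 0. The share of fragments in all promoter peaks was also higher in crypt progenitor-like than in enterocyte-like cells, 51.0% against 46.8%. Signs and counts of promoters are relative to 0, and no median over all promoters is given here. A small median above 0 therefore does not set a list apart from other promoters, and its opposite sign to the RNA has the same limit. Promoters of nutrient and ion transporters stood at -0.98 (18 of 24 below 0), of distal segment genes at -1.11 (12 of 12 below 0) and of MHC class II genes at -0.068 (4 of 9 below 0). Lipid uptake (-0.25), proximal segment (-0.26), villus tip (-0.21), immediate early (-0.014) and complex II promoters (-0.0062) also lay below 0, as did their RNA per nuclear-encoded UMI. Intervals over members included 0 for each of these lists and for MHC class II promoters. Across held-out genes, RNA and promoter ratios to enterocyte-like cells correlated with Pearson r of 0.55 in crypt progenitor-like (5640 genes, Spearman rho 0.51), 0.65 in goblet-like (5301 genes, 0.56), 0.62 in Paneth-like (4571 genes, 0.51), 0.64 in enteroendocrine-like (4467 genes, 0.50) and 0.56 in tuft-like cells (4202 genes, 0.43). These are correlations across genes of 1 animal, and genes are not independent replicates.

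The leading peaks of each class, by the lower bound of the counting interval of the ratio to all other kept cells among peaks with at least 100 counts in the class, are given in mm10 coordinates with the nearest gene start or the gene they lie in. In goblet-like cells they were chromosome 2, 170431137 to 170432001 (24.6-fold, 3291 bp from the start of Bcas1) and chromosome 6, 23075267 to 23076173 (27.6-fold, within Aass). In Paneth-like cells they were chromosome 12, 31280780 to 31281664 (29.2-fold, within the laminin gene Lamb1) and chromosome 4, 125969656 to 125970507 (26.9-fold, nearest gene Csf3r at 54042 bp). In enteroendocrine-like cells they were chromosome 15, 97271971 to 97272829 (64.5-fold, at the start of Pced1b) and chromosome 1, 72536520 to 72537335 (45.1-fold, at the start of Marchf4 and within Smarcal1). In tuft-like cells the peaks that reached this minimum were led by chromosome 14, 25317742 to 25318651 (4.65-fold, nearest start Zmiz1os1 at 139146 bp) and chromosome 14, 102982331 to 102983251 (2.99-fold, at the start of Kctd12). Promoters of the tuft markers Il25 and Alox5ap, with 28 and 17 fragments in these cells, stood higher at 25.7-fold and 22.4-fold.

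Enterocyte-like cells were led by chromosome 18, 30514332 to 30515225 (8.38-fold, 241459 bp from Pik3c3) and chromosome 2, 62451336 to 62452235 (7.22-fold, 31414 bp from the proglucagon gene Gcg). Crypt progenitor-like cells were led by chromosome 13, 29202260 to 29203161 (6.29-fold, within Cdkal1, 248546 bp from Sox4) and chromosome 5, 127282375 to 127283273 (5.78-fold, within Tmem132c).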

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

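No tests of an explanation stand in this part, so none was chosen after the result was seen, and each value is given because it lies outside the class comparisons yet above the limit that a count of 0 allows. In the barcodes that failed the filters, a median of 87.5% of UMIs came from mtDNA. Mitochondrial tRNA genes, which carry no poly(A) tail in their mature form, gave 1402 UMIs in the kept cells. Of these, 29 UMIs came from mt-Ta, the gene for the alanine tRNA that carries the mutation, and the base at the mutated position was not analysed here. The unnamed clusters held 2117 kept cells, described further on.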

How the results depend on the processing

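No tests in this part were chosen after the result was seen, but 3 alternatives were: the ceiling of 80% mtDNA-encoded UMIs, the removal of the 884 cells with the highest doublet scores and, for held-out genes, the nuclear-encoded scale. Over 134 results and 931 alternative values, 629 stayed within the 95% interval of the value reported (or within 1.5 times, for counts), 290 moved beyond it in the same direction and 12 reversed. Leaving aside the library size and the mtDNA ceilings, 333 of 389 list medians stayed within that interval, 56 moved beyond it and 0 reversed. Of 228 values for named held-out genes under the same alternatives, 176 stayed, 52 moved and 0 reversed. The library size moved a further 48 of these genes' values. All these totals of stayed values include the alternative that kept the marked doublet. It adds only 1 cell and could hardly move a value, and 133 of its 134 values stayed. For lists and genes a reversal was judged per UMI of all kinds, where no change per nuclear-encoded UMI lies at a log2 of 1.09 to 1.49 by class. A change of sign per nuclear-encoded UMI was therefore not counted as reversed. The integrated stress medians of Paneth-like and tuft-like cells made such a change with at least 100 UMIs per gene. With thinned cells, those of crypt progenitor-like, goblet-like and Paneth-like cells fell below the point of no change that holds without thinning. That point was not computed anew for alternatives that change the cells or their weight, so changes of this kind were not counted there. No paired analysis of samples was possible because both libraries are different assays on the same cells of 1 animal and share only replicate number 1. Their ratios were set side by side only across genes and gene lists. The motif alternatives were not run, since no genome sequence was used here. The ceiling of 20% left 89 cells, too few for classes, so it gives only that number. Clusters from ATAC peaks held no tuft-like class. Depth limits the small classes most, with 32.8% of simulated 2-fold changes meeting the 1.5-fold criterion in the tuft-like contrast. The moved values of named held-out genes are given by these counts alone. The other values that moved or reversed follow, as median log2 ratios to enterocyte-like cells per UMI of all kinds for gene lists, with progenitor standing for crypt progenitor-like and class names without their ending. The cause was not tested for any of them, except that the library size shifts all genes of a contrast by the same factor by construction.

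With mtDNA-encoded UMIs left out of the library size, complex I was -0.21 in progenitor, -0.49 in goblet, -0.72 in Paneth, -0.57 in enteroendocrine and -0.32 in tuft cells. Complex III was -0.39 in progenitor cells. Complex IV was -0.47 in progenitor cells. Complex V was -0.39 in progenitor cells. The unfolded protein response was 0.95 in goblet, 0.75 in Paneth, 0.36 in enteroendocrine and 0.21 in tuft cells. Integrated stress genes were 0.30 in progenitor, 0.73 in goblet, 0.72 in Paneth, 0.047 in enteroendocrine and 0.068 in tuft cells. Lipid uptake was -3.00 in progenitor, -1.80 in goblet, -2.76 in Paneth, -2.59 in enteroendocrine and -3.06 in tuft cells. Aminoacyl-tRNA synthetases were 1.38 in progenitor, 0.66 in goblet, 0.77 in Paneth, 0.80 in enteroendocrine and 0.51 in tuft cells. MHC class II was -2.16 in progenitor, -1.91 in goblet, -2.45 in Paneth, -2.81 in enteroendocrine and -2.93 in tuft cells. Wnt signalling was 1.42 in progenitor cells. Fatty acid oxidation was 0.15 in progenitor cells. TRNA processing was 1.37 in progenitor cells. MtDNA maintenance was 1.2 in progenitor cells. Mitochondrial ribosomal proteins were 0.40 in progenitor cells. MtDNA-encoded mRNA was -2.80 in progenitor, -2.04 in goblet, -2.49 in Paneth, -2.38 in enteroendocrine and -1.60 in tuft cells. Of these, complex I in all 5 classes and complexes III, IV and V in progenitor cells reversed.

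With cells above 80% mtDNA-encoded UMIs left out, the mtDNA-encoded mRNA share of UMIs was 4.37% in progenitor, 9.40% in enterocyte, 8.21% in goblet, 7.76% in Paneth, 7.16% in enteroendocrine and 9.39% in tuft cells. Of kept cells, 28.4% were progenitor-like, 13.2% were enterocyte-like, 20.3% were goblet-like, 3.90% were Paneth-like, 2.81% were enteroendocrine-like and 1.58% were tuft-like. Complex I was 0.30 in progenitor, 0.016 in goblet, 0.041 in Paneth, 0.049 in enteroendocrine and 0.17 in tuft cells. Complex III was -0.020 in progenitor cells. Complex IV was -0.029 in progenitor cells. Complex V was 0.11 in progenitor cells. The unfolded protein response was 1.43 in goblet, 1.56 in Paneth and 0.60 in tuft cells. Integrated stress genes were 0.51 in enteroendocrine and -0.51 in tuft cells. Lipid uptake was -2.66 in progenitor, -1.28 in goblet, -2.24 in Paneth, -2.26 in enteroendocrine and -2.75 in tuft cells. Aminoacyl-tRNA synthetases were 1.78 in progenitor, 1.21 in goblet, 1.48 in Paneth and 1.36 in enteroendocrine cells. MHC class II was -2.08 in progenitor, -1.79 in goblet, -2.10 in Paneth and -2.57 in tuft cells. Mitochondrial ribosomal proteins were 1.02 in progenitor cells. MtDNA-encoded mRNA was -0.96 in progenitor, -0.19 in goblet, -0.23 in Paneth, -0.28 in enteroendocrine and 0.048 in tuft cells. Of these, complexes III and IV in progenitor cells and mtDNA-encoded mRNA and the integrated stress response in tuft cells reversed.

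With each cell thinned to 500 UMIs, the mtDNA-encoded mRNA share of UMIs was 4.19% in progenitor, 13.3% in enterocyte, 6.78% in goblet, 6.18% in Paneth, 6.64% in enteroendocrine and 9.90% in tuft cells. Complex I was 0.57 in progenitor, 0.33 in goblet and 1.08 in tuft cells. Complex III was 0.21 in progenitor cells. Complex IV was 0.36 in progenitor cells. Complex V was 0.26 in progenitor cells. The unfolded protein response was 0.72 in tuft cells. Integrated stress genes were 0.57 in progenitor, 0.77 in goblet and 0.27 in Paneth cells. Lipid uptake was -1.06 in goblet and -0.42 in tuft cells. Aminoacyl-tRNA synthetases were 1.74 in Paneth, 0.97 in enteroendocrine and 0.46 in tuft cells. MHC class II was -1.28 in goblet cells. Mitochondrial ribosomal proteins were 1.05 in progenitor cells. MtDNA-encoded mRNA was -1.53 in progenitor, -0.97 in goblet and -0.31 in tuft cells. At this depth a member with 0 tuft UMIs enters at the floor of 3 counts, so the tuft medians of nuclear-encoded lists are upper limits. The same floor bears on the other small classes.

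With each cell given the same weight, the mtDNA-encoded mRNA share of UMIs was 4.17% in progenitor, 13.4% in enterocyte, 6.77% in goblet, 6.29% in Paneth, 6.54% in enteroendocrine and 10.0% in tuft cells. Complex I was 0.47 in progenitor, 0.34 in goblet, 0.57 in Paneth and 0.26 in enteroendocrine cells. Complex III was 0.33 in progenitor cells. Complex IV was 0.29 in progenitor cells. Complex V was 0.31 in progenitor cells. The unfolded protein response was 2.01 in Paneth and 0.92 in tuft cells. Integrated stress genes were 0.84 in enteroendocrine and 0.52 in tuft cells. Lipid uptake was -1.17 in goblet cells. Aminoacyl-tRNA synthetases were 2.14 in progenitor and 1.66 in enteroendocrine cells. MHC class II was -1.28 in goblet cells. Mitochondrial ribosomal proteins were 1.02 in progenitor cells. MtDNA-encoded mRNA was -0.97 in goblet, -0.91 in enteroendocrine and -0.31 in tuft cells.

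With clusters from ATAC peaks, the mtDNA-encoded mRNA share of UMIs was 16.7% in enterocyte, 9.48% in goblet, 6.54% in Paneth and 8.61% in enteroendocrine cells. Of kept cells, 30.4% were progenitor-like, 46.1% were enterocyte-like, 7.11% were goblet-like, 6.74% were Paneth-like and 3.13% were enteroendocrine-like. Correlations across genes were 0.52 for progenitor, 0.64 for Paneth and 0.62 for enteroendocrine cells. Complex III was 0.80 in progenitor cells. Complex IV was 0.80 in progenitor cells. Aminoacyl-tRNA synthetases were 1.12 in goblet cells. Transporters were -1.13 in progenitor cells. MtDNA-encoded mRNA was -0.83 in goblet, -1.31 in Paneth and -0.86 in enteroendocrine cells.

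With the 884 highest doublet scores removed, the mtDNA-encoded mRNA share of UMIs was 3.96% in progenitor, 16.5% in enterocyte, 7.60% in goblet, 7.19% in Paneth, 6.61% in enteroendocrine and 10.5% in tuft cells. Of kept cells, 50.3% were enterocyte-like and 13.4% were goblet-like. Complex I was 0.62 in enteroendocrine cells. The unfolded protein response was 2.31 in goblet cells. MtDNA-encoded mRNA was -1.92 in progenitor, -1.09 in goblet, -1.18 in Paneth and -1.24 in enteroendocrine cells. At Leiden resolution 0.5, the mtDNA-encoded mRNA share of UMIs was 5.11% in progenitor, 16.5% in enterocyte and 10.5% in tuft cells. Of kept cells, 47.4% were enterocyte-like and 1.2% were tuft-like. MtDNA-encoded mRNA was -0.92 in goblet cells. At Leiden resolution 2, the mtDNA-encoded mRNA share of UMIs was 4.76% in progenitor, 16.2% in enterocyte, 9.24% in goblet and 7.97% in Paneth cells. Of kept cells, 23.4% were progenitor-like, 37.7% were enterocyte-like and 13.1% were goblet-like. MtDNA-encoded mRNA was -0.82 in goblet cells. With at least 1000 UMIs per cell, the mtDNA-encoded mRNA share of UMIs was 4.66% in progenitor, 16.2% in enterocyte, 8.75% in goblet and 7.86% in Paneth cells. Of kept cells, 33.8% were enterocyte-like. With at least 100 UMIs per gene over both classes, integrated stress genes were 1.14 in Paneth and 0.33 in tuft cells. With at least 200 UMIs and 200 promoter counts per gene, the correlation was 0.69 for goblet, 0.60 for enteroendocrine and 0.61 for tuft cells. With the marked doublet kept, the mtDNA-encoded mRNA share of UMIs was 4.61% in progenitor cells. With a promoter window of 2 kb, the promoter share of fragments was 55.1% in progenitor, 51.1% in enterocyte, 54.7% in goblet, 55.6% in Paneth, 57.9% in enteroendocrine and 59.4% in tuft cells.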

Other observations

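Of the tests in this part, the amount of mtDNA-encoded mRNA per cell and both tests of Lars2 were chosen only after the result was seen, while the matched-depth, free RNA and doublet tests were set before their results were seen.

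A cluster of 935 cells reached no marker minimum and was left unnamed, yet showed a distinct set of genes. Its cells held mtDNA-encoded mRNA at 5.41% of UMIs, against 16.0% in enterocyte-like and 4.59% in crypt progenitor-like cells. Relative to enterocyte-like cells and per nuclear-encoded UMI, villus tip landmarks had a median log2 of -2.82 (13 of 14 lower), with Nt5e at -4.20 and Ada at -3.24. Villus base landmarks went both ways (5 higher and 5 lower of 12), with the gasdermin genes Gsdmc2 and Gsdmc4 at 4.65 (363 against 21 UMIs) and 2.52, the inflammasome gene Nlrp6 at 1.14 and the phospholipase Plb1 at -3.33. Fatty acid oxidation genes stood at 0.58 (11 higher and 1 lower of 24) and mitochondrial ribosomal proteins at 0.37 (26 higher and 1 lower of 76). Lipid uptake genes stood at -1.57 (17 of 22 lower), MHC class II genes at -1.68 (8 of 9 lower) and interferon response genes at -1.36 (13 of 22 lower). Per UMI of all kinds these ratios lie higher by 1.01, which turns none of the signs of the list medians given here.

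The other unnamed clusters differed in RNA content. A cluster of 1085 cells with mtDNA-encoded mRNA at 18.4% of UMIs was led by Atp5e, Oat, Rpl32 and Apoa4. Its highest marker list was that of enterocytes (median log2 0.92), and it was left unnamed for its low depth, a median of 431 nuclear-encoded UMIs per cell with 1 enterocyte marker among its leading genes. At Leiden resolution 0.5 there was no such cluster and 47.4% of kept cells were enterocyte-like, against 36.4%. A further 97 cells with a median doublet score of 0.206 carried markers of 2 lineages.

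The share of mtDNA-encoded mRNA was higher in enterocyte-like than in crypt progenitor-like cells. A constant amount diluted by fewer nuclear-encoded UMIs is argued against by the amount per cell, 2.90 times as high in enterocyte-like cells. Loss of cytoplasmic RNA as the whole source is argued against among cells of 1000 to 2000 nuclear-encoded UMIs, where the ratio of mtDNA-encoded mRNA to mitochondrial rRNA was still 3.28 times as high and the shares were 15.7% and 4.62%. For a like amount of free RNA per droplet, the 5th percentile of crypt progenitor-like cells was 0.124 of the difference of the class medians. Such an amount cancels out of that difference, so this test cannot decide. The percentile, 61 UMIs, is the most that a like amount allows, against a median of 669 in enterocyte-like cells. No biological explanation was tested, and survival of dissociation by different cells was not measured.

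Lars2, the mitochondrial leucyl-tRNA synthetase gene, gave 17032 UMIs per 1000000 nuclear-encoded UMIs in Paneth-like cells, 8831 in enterocyte-like cells and 5101 in enteroendocrine-like cells. Reads shared with the mitochondrial rRNA gene mt-Rnr2 could be a source, and the Lars2 to mt-Rnr2 ratio would then be alike in all classes. It differed 10.6-fold between the highest and lowest of 6 classes, which argues against such reads as the whole source. The high ratio rests on Paneth-like cells: without them it differed 2.60-fold, between the bounds set for and against, so for the other 5 classes the source cannot be told. Reads shared with nuclear rRNA were not tested.

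A goblet-like cluster of 265 cells had a median of 19841 fragments per cell, against 6972 in the largest goblet-like cluster, and median doublet scores of 0.164 against 0.0323. If droplets with a goblet-like and an enterocyte-like cell were the source, lipid and transporter genes would be higher there. They were 2.24 times as high per nuclear-encoded UMI, as that explanation needs. At Leiden resolution 0.5, goblet-like cells formed clusters of 903 and 569 cells and none like it, while resolution 2 gave one of 284 cells that was also led by Clca1, Bcas1 and Fer1l6. Doublets may therefore form part of this cluster, and a goblet subtype that absorbs lipids stays open as an untested alternative.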
